A study of Mus musculus with 18 samples.

How the data were processed

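RNA from whole mouse lung was compared between animals given bleomycin (2 U/kg) or saline into the trachea and studied 1, 2 or 3 weeks later. Per the labels, each RNA pool came from 3 male C57BL/6 animals of 8 weeks of age, and each week had 2 bleomycin pools and 1 saline pool. Each of the 9 pools was labelled through aminoallyl nucleotides and hybridised on 2 arrays against a common mouse reference RNA with the dyes exchanged, which gave 18 arrays. The pool was the replicate throughout, and the 2 arrays of a pool were not counted as replicates.

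The scanner files were made by the authors with Agilent Feature Extraction A.7.5.1. Per the file headers, the mean signal of a spot and the median of its local background are linear intensity values for each dye with no normalization. Processed signals are, per the file headers, intensity values after background subtraction, spatial detrending and a dye normalization with linear factors and LOWESS. The deposited log ratio is the log10 of processed Cy5 over processed Cy3 within an array. The deposited value table of the series holds log2 ratios of lung over reference, which was checked against the scanner log ratios of each array, where the correlation across spots ran from 0.9998 to 1.00.

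Each array held 22393 spots, of which 21318 were gene spots for 20868 probes. Mean signals less the local background median were corrected by normexp with an offset of 50 and normalized within each array by loess, with limma 3.58.1 in R 4.3.3 and with data.table (version 1.17.8). Control spots, and spots marked in either dye as non-uniform or as population outliers, had no weight and were then left out. The sign was turned to lung over reference, repeated spots of a probe were averaged, and the available arrays of a pool were averaged to 1 value. A probe was used when its lung channel was well above background on both arrays of at least 2 of the 9 pools, which 20434 probes passed. The probe with the highest mean log2 intensity stood for each gene, which left 20269 genes or unnamed probes, 9926 of them with a symbol. Of all probes, 8947 were named through their RefSeq accession in the reference table. A further 1064 were named through a symbol in the probe description found in that table and 261 by the symbol of the file alone, and 10596 had no symbol. Col1a1, Col3a1, Fn1, Cdkn1a and Blmh were not named by symbol, and probes whose descriptions name their products were chosen after their values were seen.

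Arrays have no read depth, and their number limits the precision. The lung channel was above background at 93.9% to 98.1% of gene spots per array, and between 1 and 61 gene spots per array were saturated. The spots left out for uneven pixels numbered 209 to 9607 per array. They were most frequent in bleomycin pool 2 at 2 weeks and in both bleomycin pools at 3 weeks, where 59.1%, 49.2% and 52.5% of probes were measured on both arrays. The other 6 pools had 78.1% to 97.9%. A probe measured on 1 array of a pool carries its dye effect, which had a median size of 0.08 on the log2 scale and a 99th percentile of 0.36.

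Differences were fitted with limma (lmFit and eBayes, two-sided moderated tests) and called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Bleomycin was compared with saline over all weeks with week as a term. A fit of 6 groups gave each week's difference, the changes between bleomycin weeks, the differences between saline weeks and the interaction of week and treatment. In that fit the spread came from the 3 pairs of bleomycin pools, and the lone saline pool of each week was assumed to vary like them. Errors are standard errors of the fit, and missing pools were left out gene by gene. The procedure was tested on simulated data of the same layout. For a change of 1 on the log2 scale it found 66 of 67 genes over all weeks. At 1, 2 and 3 weeks it found 45 of 67, 42 of 67 and 41 of 67, and none was in the wrong direction. The run held changes of 0.58, 1 and 2 together, and 9, 14, 13 and 10 unchanged genes were called falsely in the same order. At each single week these were more than 0.05 of all calls, with 14 beside 5, 45 and 66 found genes at 1 week. For a change of 0.58 the procedure found 46 of 67 genes over all weeks and far fewer at each week. All simulated pools, saline ones included, varied around 1 mean with the spread of the bleomycin pairs. These counts therefore do not cover a saline pool that stands apart, as that of week 2 did. No scan date or slide was shared between arrays, so no such block was fitted.

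The samples, comparisons, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. There were 36 lists. Those of matrix and its turnover were fibrillar collagens and collagen processing, matrix glycoproteins and proteoglycans, basement membrane, TGF-beta pathway and targets, and proteases and their inhibitors. Mesenchymal and vascular lists held markers of fibroblasts and myofibroblasts, smooth muscle and endothelium. Immune lists held markers of macrophages and monocytes, alternatively activated macrophages, neutrophils, T and NK cells, B and plasma cells, mast cells with eosinophils and basophils, dendritic cells with MHC class II, chemokines, cytokines with the type 2 response, interferon response and complement. Epithelial lists held markers of alveolar type I, alveolar type II, club and secretory, ciliated, and stressed and regenerating cells. Lists of cell state were p53 targets, cell cycle, antioxidant and detoxification, unfolded protein response, lipid and cholesterol synthesis, immediate early and heat shock genes, and circadian clock genes. Lists for other tissue carried over at dissection or in blood were cardiac muscle, skeletal muscle, adipose and mesothelial tissue, thymus and lymphoid tissue, and erythroid cells.

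Lists were tested with the camera formula on the moderated statistics of genes that may lack pools, with a preset correlation of 0.01 and adjustment over the 36 lists. This was repeated with a correlation estimated from the data, and with fry on genes complete in all 9 pools. Camera asks whether a list moves relative to the other genes, and fry asks whether its genes move on balance in 1 direction. Counts of list members are given over all genes and adjusted over the list alone.

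The rule for named genes took, over all weeks, the 12 largest rises and 12 largest falls among called genes with the same direction in all 6 bleomycin pools. It took 8 rises and 8 falls for each week, 6 each way between bleomycin weeks and the 10 smallest adjusted p of the interaction, always among called genes with a symbol. From each list it took up to 4 called members, or else up to 2 members with the largest moderated statistics, and 18 genes were named whatever their values. List members named at 1 week and between bleomycin weeks 3 and 1 were chosen after their values were seen. No fold is given for Scgb1a1, whose spot was saturated on all 18 arrays, nor for Ctla4, which was not above background in the saline pool of 3 weeks.

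The alternatives were Agilent's processed signals, no background correction, an offset of 16, median centring, scale and Aquantile normalization, the series value table, no filter on dim probes, probes above background on all 18 arrays, uneven spots kept, all probes of a gene, arrays of 1 dye orientation, all 18 arrays with the pool as a random block, array weights, a trended robust prior and limma treat for a fold over 1.2. Further ones changed the week term, the control pools, the pools in each fit, the replicate block and the set test, and left out each pool and each array. Alternatives on the dye effect, the 2-week saline pool and its Cy3 array, genes complete in all pools, the saline pools of weeks 1 and 3 as control for week 2 and those of weeks 1 and 2 for week 3, and the 3 pools with many uneven spots were added after seeing the data. The endotoxin arm of the study was not analysed here. The result of 1 gene that the rule named is not reported here.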

Results

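Gene expression was measured in mouse lung at 1, 2 and 3 weeks after bleomycin, a DNA-damaging drug used to produce lung injury and scarring, or after saline. The title of the series sets this model beside long-term exposure to endotoxin. Each week had 2 bleomycin pools and 1 saline pool of lung RNA from 3 animals each, every pool read on 2 arrays of opposite dye orientation. The median lung signal per array ran from 309 to 1089 intensity units. It was 720 to 1089 in the bleomycin pools of week 3, 309 and 332 in the saline pool of week 3, and 340 to 473 in the bleomycin pools of week 1. Bleomycin pool 2 of week 2 had 806 and 1014, and the 2-week saline pool 351 on its Cy3 array and 786 on its Cy5 array. Comparisons of these groups set brighter arrays against dimmer ones, and no fit tested brightness by itself. The 3 pools with many uneven spots were also the brightest in each dye orientation. Fits that treat these pools apart cannot separate uneven spots from brightness. The 2 arrays of a pool correlated across probes at 0.769 to 0.906, and the bleomycin pools of a week correlated across genes at 0.908, 0.905 and 0.889 at weeks 1, 2 and 3. The saline pool of week 2 stood apart, with a median correlation of 0.721 with the other pools against 0.840 to 0.896 for the rest. Genes are not independent replicates, so these correlations carry no p.

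Across all weeks, bleomycin lungs held more RNA for matrix proteins, for enzymes that turn them over and for macrophage genes than saline lungs. Spp1, which encodes the secreted matrix protein osteopontin, rose 20.9-fold (log2 4.39 ± 0.47 SE, adjusted p = 0.00897), and Tnc, the matrix glycoprotein tenascin C, rose 5.48-fold (2.45 ± 0.14, adjusted p = 0.000354), each in 6 of 6 pools. The lung signal of Spp1 was saturated on 1 of the 18 arrays. Mmp12, the macrophage elastase, rose 6.35-fold (2.67 ± 0.35, adjusted p = 0.0258) in 6 of 6 pools, and the metalloprotease inhibitor Timp1 rose 4.16-fold (2.06 ± 0.19, adjusted p = 0.00810) in 5 of 5. Collagen chains rose as well: Col5a2 3.16-fold, Col1a2 2.64-fold and Col5a1 2.44-fold. Here and below, the rule took the largest rises and falls only from genes with 1 direction in all 6 pools. For them 6 of 6 was fixed beforehand and is no support of its own. The 2 bleomycin pools of a week also share 1 saline pool.

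Of 16 measured members of the fibrillar collagen list 3 rose and none fell, with 7 higher adjusted over the list alone and a median of 0.30 on the log2 scale. The list was called (adjusted p = 6.72e-06), with adjusted p = 0.0550 with an estimated correlation. Col1a2 (1.40 ± 0.15, adjusted p = 0.00828) was measured in all 6 bleomycin pools and higher in each. Some probes without a symbol were chosen after their values were seen and are named here by their descriptions. They rose for the type I procollagen alpha 1 chain (2.04 ± 0.19, adjusted p = 0.00560) and a type III collagen alpha 1 homolog (1.49 ± 0.19, adjusted p = 0.0212) in 6 of 6 pools. The probe described as fibronectin rose 7.10-fold (2.83 ± 0.25, adjusted p = 0.00394) in 6 of 6 pools. Of 25 matrix glycoproteins 3 rose, namely Spp1, Tnc and Aspn (0.76 ± 0.11), with 12 higher and 1 lower adjusted over the list alone and a median of 0.47. Their list had adjusted p = 1.79e-08, and adjusted p = 0.162 with an estimated correlation. Aspn and Mmp12 were above background on 1 of the 2 arrays of the 1-week saline pool.

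Basement membrane genes numbered 13, with none called over all genes, 4 higher adjusted over the list alone and a median of 0.21 (adjusted p = 0.000242, and adjusted p = 0.135 with an estimated correlation). Col4a1, a chain of type IV collagen, was at 1.11 without passing on its own. The TGF-beta list had 1 riser among 20 members, Ccn2 (1.15 ± 0.19, adjusted p = 0.0471), a matricellular target of TGF-beta, with 6 higher adjusted over the list alone and a median of 0.26. This list had adjusted p = 6.72e-06, and adjusted p = 0.288 with an estimated correlation. Its median was 0.14 without the 2-week saline pool, and that of basement membrane genes 0.40 without the 1-week one, both still called. Among 24 proteases and inhibitors 5 rose, which were Mmp12, Timp1, cathepsin S (Ctss, 1.89 ± 0.26), the plasminogen activator Plau (0.85 ± 0.12) and Adamts1 (0.77), with 10 higher adjusted over the list alone and a median of 0.22. The protease list was called with the preset correlation (adjusted p = 2.17e-08), with an estimated one (adjusted p = 0.0411) and by fry (adjusted p = 0.00311). Its median was 0.35 without the saline pool of week 2 or of week 3.

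Macrophage genes formed the group with the highest median. Of 18 macrophage and monocyte markers 6 rose and none fell, with 11 higher and 1 lower adjusted over the list alone and a median of 0.79 (adjusted p = 7.53e-14, and adjusted p = 0.0643 with an estimated correlation). Among them were the Fc receptor chain Fcer1g (1.34 ± 0.13), the monocyte chemokine receptor Ccr2 (1.29 ± 0.21), the phagocyte glycoprotein Cd68 (1.16 ± 0.14) and the scavenger receptor Msr1 (1.06 ± 0.15), beside Ctss and the lysosomal protein Laptm5 (0.92). Alternatively activated macrophage markers included the resistin-like protein Retnla, which rose 6.97-fold (2.80 ± 0.21, adjusted p = 0.00108) in 6 of 6 pools. That list held 13 genes, 2 risers, 5 higher adjusted over the list alone and a median of 0.30 (adjusted p = 5.85e-05, and adjusted p = 0.0550 with an estimated correlation). Without the 2-week saline pool that median was 0.16 and the list still called. Arg1 was at 1.01 ± 0.28 (adjusted p = 0.218) and Chil3 at -0.77 ± 0.38 (adjusted p = 0.593), neither of which passed.

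Of 28 chemokines Ccl9 (1.53 ± 0.15, adjusted p = 0.00748) and Ccl12 (0.79 ± 0.12, adjusted p = 0.0387), which attract monocytes, rose, while Ccl2 stood at -0.06 ± 0.14. The chemokine list had 7 members higher adjusted over the list alone and a median of 0.10 (adjusted p = 0.000160, and adjusted p = 0.0550 with an estimated correlation), which ran from 0.06 without bleomycin pool 2 of week 1 to 0.24 without the 3-week saline pool and was 0.15 without bleomycin pool 1 of week 2. The interferon response list was higher with a median of 0.22, a higher mean in 5 of 6 pools and none of its 21 members called over all genes or adjusted over the list alone. Its test gave adjusted p = 0.00145, and adjusted p = 0.312 with an estimated correlation, and Rsad2 was at 0.42. Without the 2-week saline pool the interferon list was not called (median 0.06, adjusted p = 0.112, in a range over the settings from 7.71e-05 to 0.312). Complement had 16 measured members, none called, 4 higher adjusted over the list alone, a higher mean in 4 of 6 pools and a median of 0.28 (adjusted p = 0.0303, and adjusted p = 0.312 with an estimated correlation), with C1qc at 1.21 and C1qa at 0.87. The complement list lost its call without the saline pool of week 2 (0.16, adjusted p = 0.103) or 3 (0.15, adjusted p = 0.239), without bleomycin pool 2 of week 2 (0.21, adjusted p = 0.0667) and without pool 1 (0.21, adjusted p = 0.0573) or 2 (0.29, adjusted p = 0.0548) of week 3. It passed in 14 of 36 settings, whose adjusted p ran from 0.000148 to 0.738. The acute phase gene Saa3 (3.61-fold) and the growth factor Igf1 (3.31-fold), in none of these lists, rose in 6 of 6 pools, with adjusted p of 0.0340 and 0.0284.

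Genes of airway secretory cells were lower. The club cell list had a median of -0.47 over 19 members and a lower mean in 5 of 6 pools. None of its members passed over all genes and 4 were lower adjusted over the list alone (adjusted p = 7.09e-06, and adjusted p = 0.145 with an estimated correlation). Its members Fmo2, a monooxygenase, and Por, the reductase that serves P450 enzymes, stood at -1.12 ± 0.23 and -0.62. Antioxidant and detoxification genes had a median of -0.11 over 27 members and a lower mean in 4 of 6 pools, with 1 faller, the glutathione transferase Gstm1 (-0.67 ± 0.11, adjusted p = 0.0426), and with 2 higher and 6 lower adjusted over the list alone. The test of that list gave a lower level (adjusted p = 0.0234, and adjusted p = 0.135 with an estimated correlation). The call was lost without the 1-week saline pool (-0.14), the 3-week one (-0.02) or bleomycin pool 1 or 2 of week 3 (-0.10 each), and the median was -0.07 without the 2-week saline pool. The list of stressed and regenerating epithelium was higher, with a median of 0.34 over 16 members, 2 of them higher adjusted over the list alone (adjusted p = 8.15e-05, and adjusted p = 0.0631 with an estimated correlation). Its member Clu, an extracellular chaperone, was called over all genes (0.91 ± 0.15, adjusted p = 0.0478). Without the 2-week saline pool the list's median was 0.10, still called. Of the lists named so far as higher over all weeks, the mean was higher in 6 of 6 pools except for interferon and complement.

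Cycling genes were higher with a median of 0.18 over 29 members and a higher mean in 4 of 6 pools. Top2a (2.09-fold, adjusted p = 0.0131) and Cdk1 (1.87-fold, adjusted p = 0.0258), which serve chromosome untangling and entry into mitosis, rose in 6 of 6 pools, and 5 members were higher adjusted over the list alone. The list had adjusted p = 6.62e-05, adjusted p = 0.417 with an estimated correlation, and its direction turned with scale normalization of the arrays (adjusted p = 0.944, the highest over the 36 settings, the lowest being 6.29e-11). Its call was lost without the 1-week saline pool (median 0.02, adjusted p = 0.133), and its median was 0.32 without the 3-week one. The histone gene H3c7 rose 2.37-fold. The p53 list had a median of 0.17 over 19 members and a higher mean in 5 of 6 pools, with none called and 1 higher adjusted over the list alone (adjusted p = 0.0214, and adjusted p = 0.288 with an estimated correlation). That call was lost without the saline pool of week 1 (0.16, adjusted p = 0.133) or 2 (0.06, adjusted p = 0.111) and without bleomycin pool 2 of week 3 (0.09, adjusted p = 0.0995), in a range over the settings from 0.00104 to 0.288. The p53 target Ccng1 was at 0.64, and a probe described as the cyclin-dependent kinase inhibitor 1A at 0.07 ± 0.36, with 0.84, 0.44 and -1.07 at weeks 1, 2 and 3, none of which passed, and higher in 4 of 6 pools. Cardiac muscle genes, which reach lung samples with vessel or heart tissue, had a median of -0.19 over 17 members and a lower mean in 6 of 6 pools. None of them was called over all genes and 3 were lower adjusted over the list alone (adjusted p = 5.32e-05, and adjusted p = 0.0646 with an estimated correlation). Other genes that fell in 6 of 6 pools were Letm1, a mitochondrial ion transporter (-1.67 ± 0.28), the methyltransferase Inmt (-1.36 ± 0.22), carbonic anhydrase Car3 (-0.95 ± 0.16), Acoxl and Cst10 (each -0.83) and the ubiquitin protease Usp48 (-0.81 ± 0.12).

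In total 76 of 20261 genes passed over all weeks in limma, 65 higher and 11 lower, and 1945 had an unadjusted p under 0.05. Of the 76, 53 had a symbol and 41 changed over 2-fold. Of them, 55 higher and 9 lower ones had a value in all 6 bleomycin pools and moved the same way in each. The rest include genes that lack a pool, such as Timp1, which was higher in all 5 pools where it was measured. With a term for the 3 pools with many uneven spots, added after seeing the data, 3 genes were called, which were Tnc (2.24 ± 0.15), Retnla (2.51 ± 0.22) and 1 unnamed probe. Those pools also had the brightest arrays, so that fit cannot separate uneven spots from brightness. In that fit 76 of 76 kept their direction and an unadjusted p under 0.05, which was likely beforehand, as they were chosen by their p in these pools. Without the 2-week saline pool 25 were called, 19 of them shared with the 76, and without the 3-week saline pool 6. Without bleomycin pools 1 and 2 the count was 13 and 14 for week 1, 12 and 39 for week 2, and 20 and 11 for week 3. Over all settings it ran from 2, without the 3 pools with many uneven spots, to 1750 with array weights.

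**Figure D1:**
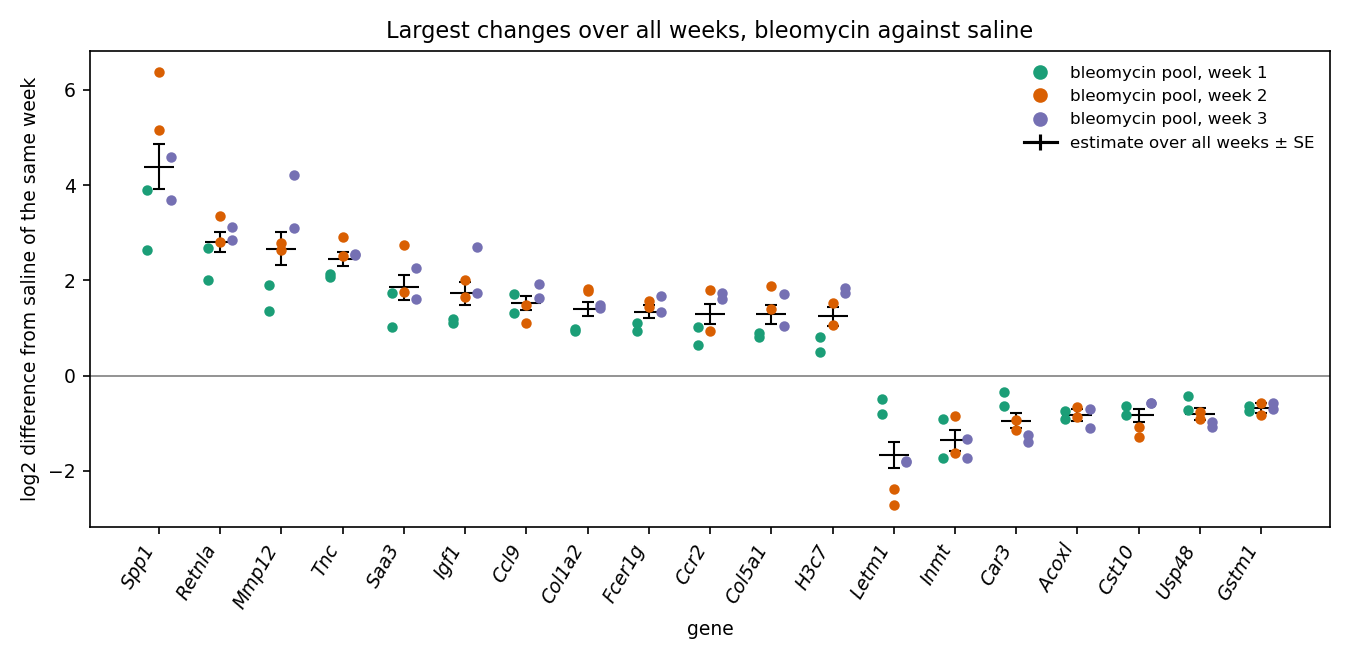
Differences from the saline pool of the same week (log2) of the named called genes in each of the 6 bleomycin pools, coloured by week, with the estimate over all weeks and its standard error in black. Spp1 has the highest mean, 4.39, and Letm1 the lowest, -1.67.

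**Figure D2:**
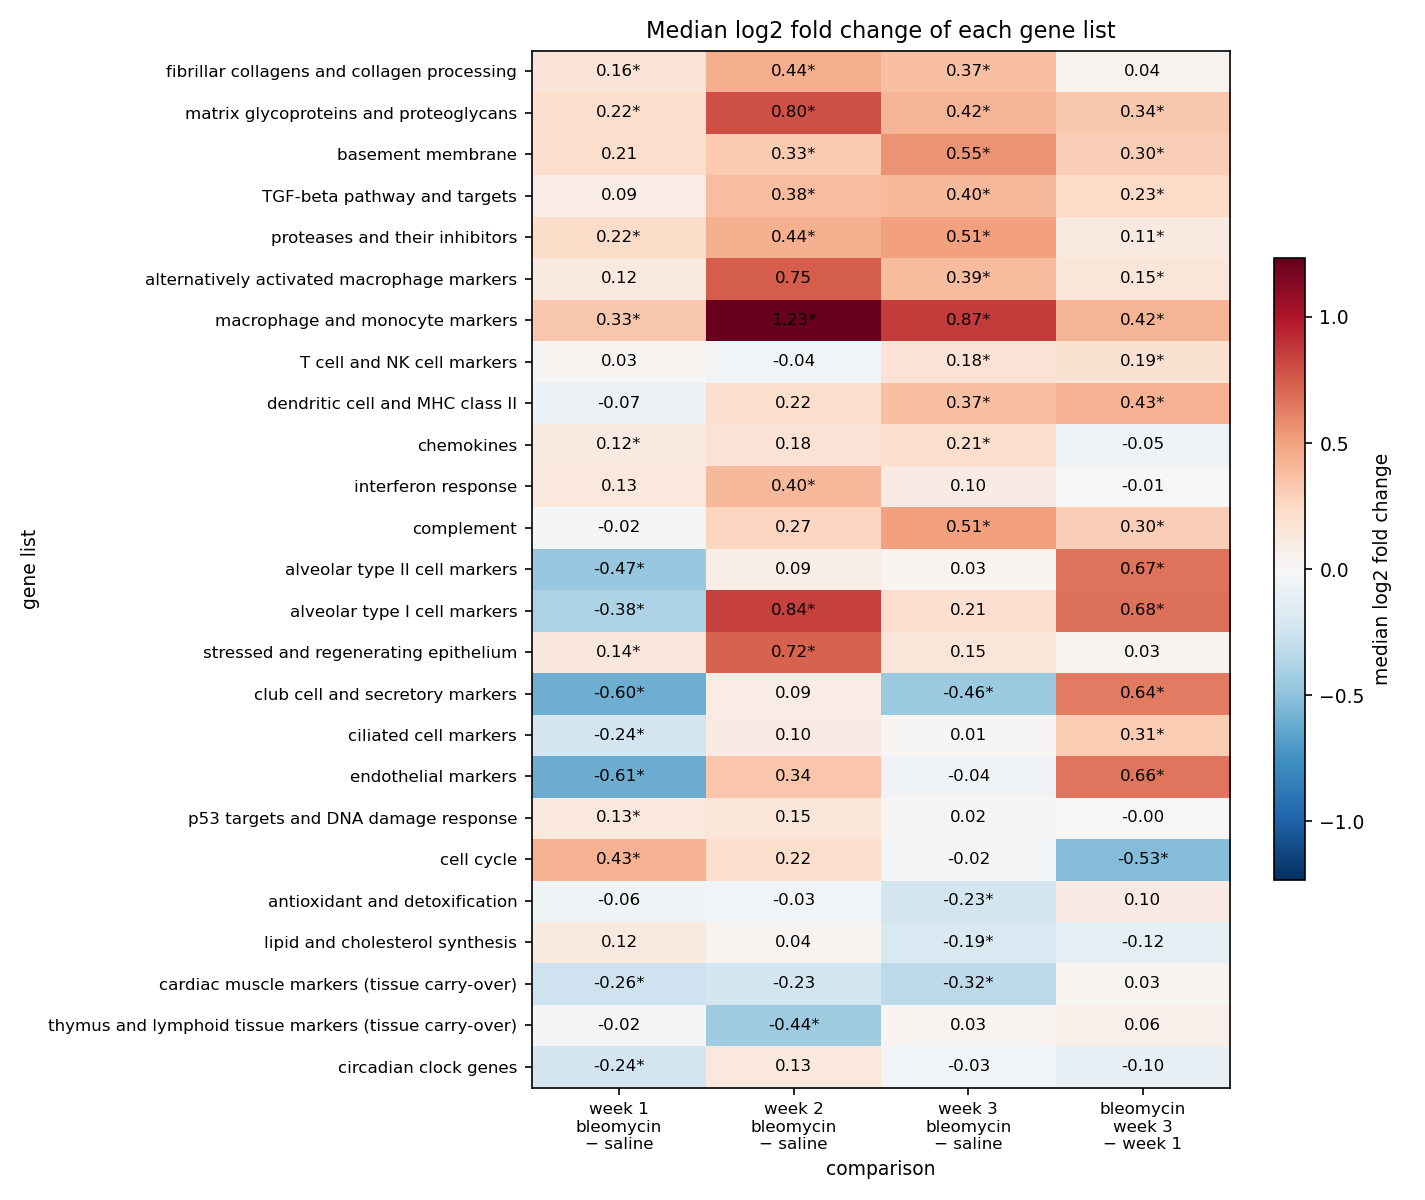
Median log2 fold change of the members of each gene list called in at least 1 of the 4 columns, which are bleomycin against saline at weeks 1, 2 and 3 and bleomycin week 3 against week 1, with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. The macrophage list runs from 0.33 at week 1 to 1.23 at week 2 against saline, and the endothelial list from -0.61 at week 1 to 0.66 between bleomycin weeks 3 and 1.

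At 1 week after bleomycin, camera with the preset correlation placed the club, alveolar and endothelial lists lower and the cycling and macrophage lists higher. With an estimated correlation it called 0 of the 36 lists. The SD of the log2 ratios was 0.52 to 0.60 on the bleomycin arrays of that week and 0.67 and 0.69 on its saline arrays. Whether this narrower spread moved the lists was not settled here. The endothelial list had a median of -0.61 with no member past the test adjusted over the list alone (adjusted p = 7.98e-10, and adjusted p = 0.414 with an estimated correlation). The club cell list had a median of -0.60 and 8 members lower adjusted over the list alone, among them the naphthalene-metabolising Cyp2f2 (-1.88 ± 0.42), Fmo2 (-1.61 ± 0.19), the carbonyl reductase Cbr2 (-1.49 ± 0.21) and the secretoglobin Scgb3a2 (-1.40). Its adjusted p was 1.60e-09, and adjusted p = 0.414 with an estimated correlation. Alveolar type II markers had a median of -0.47 (adjusted p = 2.25e-05, and adjusted p = 0.420 with an estimated correlation) and type I markers -0.38 (adjusted p = 0.0115, and adjusted p = 0.496 with an estimated correlation). The cell cycle list had a median of 0.43 and 5 members higher adjusted over the list alone, with the licensing factor Mcm2 at 0.80 and the spindle checkpoint gene Mad2l1 at 0.88. Its test was called (adjusted p = 7.98e-10, and adjusted p = 0.430 with an estimated correlation). Members named in this paragraph were chosen after their values were seen.

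Macrophage markers at 1 week had a median of 0.33, and Cd68 (1.19), Fcer1g, Ctss, Msr1 and Laptm5 were higher adjusted over the list alone (list adjusted p = 6.25e-05, and adjusted p = 0.414 with an estimated correlation). The protease list had a median of 0.22 with 6 members higher adjusted over the list alone (adjusted p = 4.11e-05, and adjusted p = 0.414 with an estimated correlation), and was the 1 list called by fry (adjusted p = 0.0284). Collagens (median 0.16, adjusted p = 0.000368), chemokines (0.12, adjusted p = 0.000949), cardiac muscle (-0.26, adjusted p = 0.00162), stressed epithelium (0.14, adjusted p = 0.00627) and circadian clock genes (-0.24, adjusted p = 0.0172) each had adjusted p = 0.414 with an estimated correlation. Matrix glycoproteins (0.22, adjusted p = 0.00895) had adjusted p = 0.471, and p53 targets (0.13, adjusted p = 0.0177) and ciliated cells (-0.24, adjusted p = 0.0475) adjusted p = 0.496, with an estimated correlation. Over all genes limma called 0 of 20123 genes at 1 week, and 1461 had an unadjusted p under 0.05; Tnc stood at 2.11 ± 0.20. Without the Cy3 array of the 1-week saline pool 182 genes were called, without its Cy5 array 1 gene, and without either 2-week bleomycin pool 2. Array weights gave 1557 and the 3 pools of that week alone 392.

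At 2 weeks matrix and macrophage genes were higher in bleomycin lungs with either choice of saline control. Spp1 rose by 5.76 ± 0.63 on the log2 scale (adjusted p = 0.00849), Retnla by 3.09 ± 0.32 (adjusted p = 0.00735), Mmp12 by 2.72 ± 0.42 (adjusted p = 0.0179) and Tnc by 2.70 ± 0.20 (adjusted p = 0.00369). Set against the saline pools of weeks 1 and 3, a control added after seeing the data, these genes were still called, with Spp1 at 4.66 ± 0.49, Mmp12 at 3.03 ± 0.32, Tnc at 2.61 ± 0.17 and Retnla at 2.32. With either control Igf1, Col1a2, Col5a2, Cd68, Ccl9, Fcer1g, Ctss and Plau rose, and Letm1 and Olfr1179 fell. Timp1 also rose with either control, but it had no value in bleomycin pool 2 of week 2.

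The week-matched comparison called 1893 of 20151 genes, 830 higher and 1063 lower, with 6139 at an unadjusted p under 0.05, and it rests on the 2-week saline pool that stood apart. Against the other saline pools 55 were called, 50 of them higher, and 40 were called with both controls, 37 in the same direction, where 5.17 were expected; the same bleomycin pools enter both. Genes among the largest changes moved with that pool. The iron carrier Trf was at 2.61 ± 0.43 against its own week and 0.00 against the other saline pools, Nudc at 2.57 and -0.12. Akt1s1, whose spot was saturated on 5 of the 18 arrays, was at 2.46 and 0.09, and the antimicrobial lectin Reg3g at 2.45 and 1.12. Among the falls, the endothelial adhesion gene Icam2 was at -2.80 and -0.14, Syt7 at -2.56 and 0.22, the transcription factor Tfcp2l1 at -2.77 and -1.57, and the olfactory receptor Olfr460 at -3.25 and 0.35. Mad1l1 was at -2.28 and 0.09, and the ciliary transport gene Ift140 at -2.25 and 0.01. Olfr1179 was at -3.74 and -1.68, called with both controls, and was above background on 1 of 2 arrays of each of the saline pools of weeks 1 and 3. Counts of calls ran from 187 without either 1-week bleomycin pool to 2830 without either 3-week bleomycin pool, and were 792 and 784 without bleomycin pools 1 and 2 of week 2. With single arrays left out they ran from 541 (bleomycin 1-week pool 2, Cy3) to 4815 (2-week saline, Cy3).

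Of the 36 lists 10 were called at 2 weeks, and with an estimated correlation none was. Macrophage markers had a median of 1.23 with 12 risers and 1 faller over all genes and 14 and 1 adjusted over the list alone (adjusted p = 4.36e-06, and adjusted p = 0.460 with an estimated correlation). Matrix glycoproteins had a median of 0.80 and 9 risers, 13 adjusted over the list alone (adjusted p = 0.000255, and adjusted p = 0.511 with an estimated correlation). The TGF-beta list had a median of 0.38 and 6 risers, 7 adjusted over the list alone (adjusted p = 0.000255, and adjusted p = 0.460 with an estimated correlation). Proteases had a median of 0.44 with 9 risers and 1 faller, 11 and 2 adjusted over the list alone (adjusted p = 0.00930, and adjusted p = 0.460 with an estimated correlation). Collagens (median 0.44, 6 risers, adjusted p = 0.0270) had adjusted p = 0.515 with an estimated correlation, and so did basement membrane genes (0.33, adjusted p = 0.0298). The remaining calls were alveolar type I markers (0.84, adjusted p = 0.0137, and adjusted p = 0.586 with an estimated correlation) and stressed epithelium (0.72, adjusted p = 0.0137, and adjusted p = 0.460 with an estimated correlation). Thymus and lymphoid genes were lower (-0.44, adjusted p = 0.0270, and adjusted p = 0.462 with an estimated correlation) and the interferon response higher (0.40, adjusted p = 0.0298, and adjusted p = 0.553 with an estimated correlation). Against the saline pools of weeks 1 and 3 the macrophage (0.51), collagen (0.35), protease (0.39), matrix (0.38), TGF-beta (0.13) and basement membrane (0.19) lists were higher and the club (-0.51), alveolar type II (-0.33) and endothelial (-0.38) lists lower, among 14 called. The other 4 lists called in the matched comparison were not called against those pools, with alveolar type I markers turned to -0.11, stressed epithelium at 0.09, thymus and lymphoid genes at -0.14 and the interferon response at 0.07.

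At 3 weeks the elastase Mmp12 reached 12.6-fold (3.65 ± 0.42 on the log2 scale, adjusted p = 0.0340), with Retnla at 2.98 ± 0.32 (adjusted p = 0.0294), Tnc at 2.55 (adjusted p = 0.0211) and Ctss at 2.46 ± 0.16 (adjusted p = 0.0211). Lox, the enzyme that crosslinks collagen and elastin, rose 3.66-fold (1.87 ± 0.17, adjusted p = 0.0284), while between bleomycin weeks 3 and 1 it differed by 0.04 and between the saline pools of those weeks by -1.27. Crybb3 (2.70 ± 0.24), the testis kinase Tssk1 (2.31 ± 0.25) and the antithrombin gene Serpinc1 (2.29 ± 0.28) were the other large rises. The falls were Letm1 (-1.79 ± 0.21), the smooth muscle myosin Myh11 (-1.57 ± 0.18), which was at -0.71 in the 2-week bleomycin pools against the saline pools of weeks 1 and 3, and the immune GTPase Gimap6 (-1.50 ± 0.16). With the 3 saline pools as 1 control Mmp12, Retnla, Tnc, Ctss and Letm1 were still called. Crybb3 (1.22), Tssk1 (0.70), Serpinc1 (0.81), Lox (0.85), Myh11 (-0.16) and Gimap6 (-0.29) were not. None of these 11 genes was called without either 1-week bleomycin pool, and Retnla, Lox, Letm1, Myh11 and Gimap6 also lost their calls without bleomycin pool 1 of week 3.

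In the lists at 3 weeks, macrophage markers had a median of 0.87, with 3 risers and 11 adjusted over the list alone (adjusted p = 2.93e-09, and adjusted p = 0.244 with an estimated correlation). Proteases had a median of 0.51, 3 risers and 11 adjusted over the list alone (adjusted p = 7.90e-07, and adjusted p = 0.244 with an estimated correlation). Matrix glycoproteins (0.42, adjusted p = 5.18e-06) and basement membrane (0.55, adjusted p = 0.00213) had adjusted p = 0.254 with an estimated correlation, as did T and NK cell markers (0.18, adjusted p = 0.0219). Collagens (0.37, adjusted p = 0.000516), alternatively activated macrophages (0.39, adjusted p = 0.00258), the TGF-beta list (0.40, adjusted p = 0.00709), chemokines (0.21, adjusted p = 0.00709) and antioxidant genes (-0.23, adjusted p = 0.00213) had adjusted p = 0.244 with an estimated correlation. Club cell genes were lower (-0.46, adjusted p = 0.000624, and adjusted p = 0.467 with an estimated correlation), and dendritic cell and MHC class II genes higher (0.37, adjusted p = 0.00813, and adjusted p = 0.475 with an estimated correlation). Complement (0.51, adjusted p = 0.0155), cardiac muscle (-0.32, adjusted p = 0.00207) and lipid synthesis (-0.19, adjusted p = 0.0219) had adjusted p = 0.268 with an estimated correlation.

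Over all genes 32 of 19398 were called at 3 weeks, 27 higher and 5 lower, and 2580 had an unadjusted p under 0.05. The count was 0 without either 1-week bleomycin pool, 113 without either 2-week one, and 10 and 169 without bleomycin pools 1 and 2 of week 3. It was 2 without the Cy5 array of bleomycin pool 1 of week 3 and 154 without the Cy3 array of the 3-week saline pool. With Agilent's processed signals, the series value table or array weights it was 0. Against the saline pools of weeks 1 and 2, a control added after seeing the data, the 32 genes kept a median share of 0.861 of their log2 change (quartiles 0.179 and 0.991), and 5 turned round.

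Between 1 and 3 weeks after bleomycin, camera with the preset correlation placed the endothelial, alveolar and antigen-presenting lists higher and the cycling list lower. With an estimated correlation it called 0 of the 36 lists. The endothelial list had a median of 0.66 and 13 members higher adjusted over the list alone, among them the receptors Tek (2.01) and Kdr (1.35 ± 0.17) and the junction gene Cldn5 (1.09). The list had adjusted p = 1.67e-10, and adjusted p = 0.365 with an estimated correlation. Alveolar type II markers had a median of 0.67 and 9 such members, with the lamellar body genes Lamp3 (1.27) and Abca3 (0.76) and the surfactant protein Sftpd (0.92 ± 0.13), at adjusted p = 1.05e-06, and adjusted p = 0.365 with an estimated correlation. Alveolar type I markers had a median of 0.68 and 5 such members, with the water channel Aqp5 at 1.18 (adjusted p = 0.000400, and adjusted p = 0.458 with an estimated correlation). The cell cycle list had a median of -0.53 and 10 members lower adjusted over the list alone, with the nucleotide reductase Rrm2 at -2.09 ± 0.17 and the kinase Ttk at -1.23 (adjusted p = 6.52e-08, and adjusted p = 0.458 with an estimated correlation). These members were chosen after their values were seen.

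Dendritic cell and MHC class II genes had a median of 0.43 and 7 members higher adjusted over the list alone, H2-Aa being at 1.87 ± 0.23 and the master regulator Ciita at 1.01 (adjusted p = 1.05e-06, and adjusted p = 0.365 with an estimated correlation). Macrophage markers (0.42, adjusted p = 3.43e-06), basement membrane (0.30, adjusted p = 0.000848), complement (0.30, adjusted p = 0.00131), the TGF-beta list (0.23, adjusted p = 0.0247), T and NK cells (0.19, adjusted p = 0.0278), proteases (0.11, adjusted p = 0.0386) and alternatively activated macrophages (0.15, adjusted p = 0.0391) were higher. Each of these had adjusted p = 0.365 with an estimated correlation. Club cell genes were higher (0.64, adjusted p = 5.53e-05, and adjusted p = 0.446 with an estimated correlation), as were matrix glycoproteins (0.34, adjusted p = 0.000416, and adjusted p = 0.372 with an estimated correlation) and ciliated cell genes (0.31, adjusted p = 0.0386, and adjusted p = 0.578 with an estimated correlation). Single genes did not pass, as limma called 0 of 19493 between weeks 3 and 1 with 3318 at an unadjusted p under 0.05. Without either 2-week bleomycin pool it called 468, and without the Cy3 array of bleomycin pool 2 of week 2 it called 251. Both 3-week bleomycin pools are among the 3 with many uneven spots. Their arrays also had higher median lung signals than those of the 1-week bleomycin pools. The SD of the log2 ratios was 0.63 to 0.77 on the 3-week bleomycin arrays and 0.52 to 0.60 on the 1-week ones. Whether this wider spread moved the lists was not settled here.

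Between bleomycin weeks 2 and 1 and weeks 3 and 2 limma called 0 of 20246 and 0 of 19480 genes, with 870 and 1299 at an unadjusted p under 0.05. Fits to the 6 bleomycin pools alone, with or without the pool number as a block, called 0 in each of the 3 comparisons. From week 1 to week 2 the endothelial list was higher (0.36, adjusted p = 6.34e-08, and adjusted p = 0.393 with an estimated correlation), the macrophage list higher (0.28, adjusted p = 2.05e-06, and adjusted p = 0.337 with an estimated correlation). The cell cycle list was lower (-0.28, adjusted p = 5.33e-07, and adjusted p = 0.405 with an estimated correlation), among 14 called. From week 2 to week 3 alveolar type II markers were higher (0.55, 6 adjusted over the list alone, adjusted p = 1.94e-07, and adjusted p = 0.572 with an estimated correlation). Collagens were lower (-0.26, adjusted p = 0.00730, and adjusted p = 0.572 with an estimated correlation), among 8 called. Without bleomycin pool 1 of week 2, 10 genes were called between weeks 2 and 1.

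The effect of bleomycin differed between weeks for 35 of 19197 genes by the interaction of week and treatment, and 4206 had an unadjusted p under 0.05. Myh11 had the smallest adjusted p (0.0127), with its effect higher by 2.74 at 2 weeks and different by -1.27 at 3 weeks from that at 1 week. Next came Syt7 (-2.52 and 0.83, adjusted p = 0.0165), a sensor for exocytosis, then Klhl1 (-2.68 and 1.33), Mad1l1 (-1.89 and 1.35), Akt1s1 (1.64 and -1.85, on the partly saturated spot) and the thioesterase Acot1 (1.97 and -0.81), each at adjusted p = 0.0241. The Wnt co-receptor Lrp5 (2.00 and -0.61), the inhibitory Smad6 (1.88 and -0.68), the methyltransferase Tpmt (-1.18 and 1.38) and the oocyte histone H1f8 (1.40 and -1.71) followed at adjusted p = 0.0273. In 35 of 35 genes the 2-week saline pool lay outside the other saline pools, and the range of the saline pools had a median of 2.72 against 0.44 for the bleomycin week means. The count was 0 without either 1-week bleomycin pool, and 62 and 151 without bleomycin pools 1 and 2 of week 3.

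**Figure D3:**
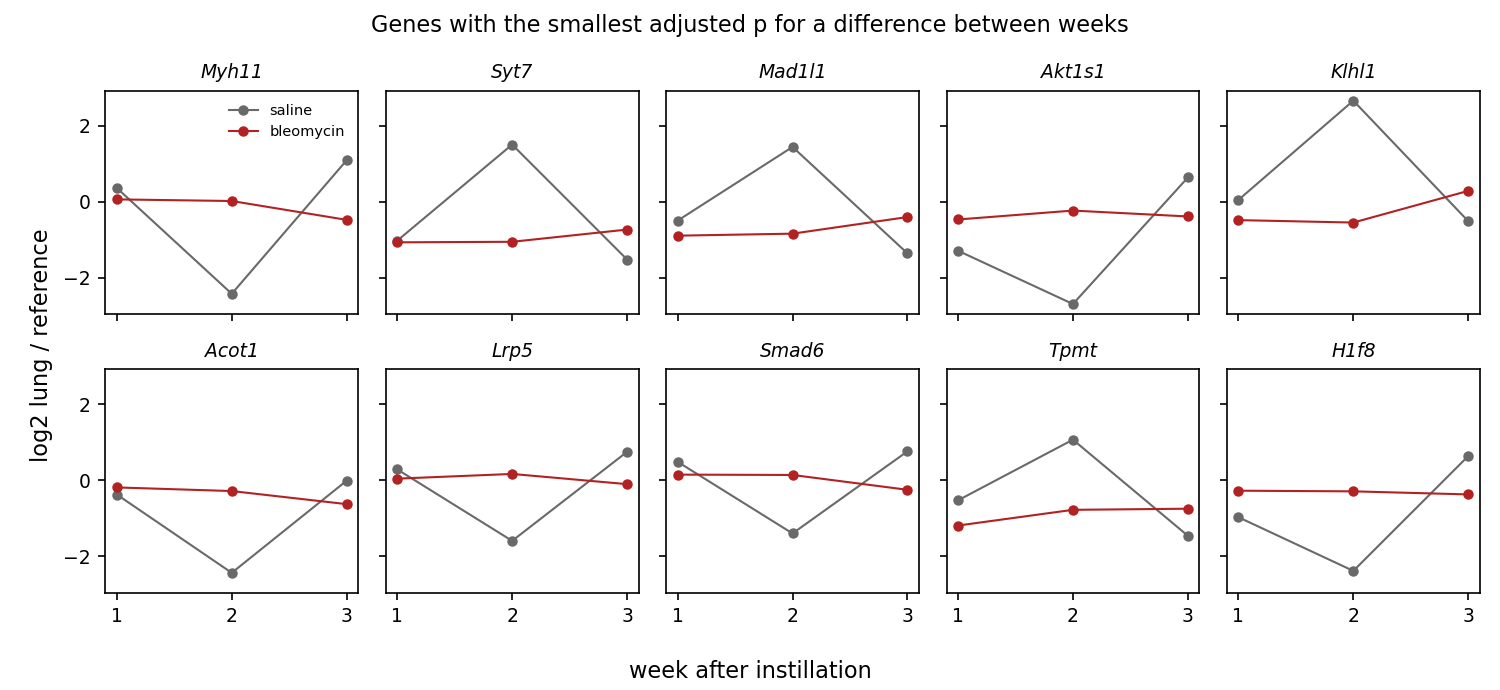
Log2 ratios of lung over reference by week for the 10 genes with the smallest adjusted p of the interaction, with the saline pool in grey and the mean of the 2 bleomycin pools in red. In each of them the saline pool of week 2 lies outside the other 2, as for Myh11 with -2.43 against 0.36 and 1.09 at weeks 1 and 3. For Akt1s1 (-1.29, -2.69 and 0.64 at weeks 1, 2 and 3) and H1f8 the saline pools of weeks 1 and 3 lie farther from each other than those of weeks 1 and 2.

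Each comparison of saline weeks set 1 pool against 1 pool, with the spread taken from the pairs of bleomycin pools, so its counts cannot separate weeks from single pools. On that footing limma called 222 of 20028 genes between weeks 2 and 1 (146 higher, 76 lower) and 1 of 20012 between weeks 3 and 1, an unnamed probe, with 5039 and 1196 at an unadjusted p under 0.05. The SD of the log2 difference across genes was 0.50, 0.30 and 0.61 between saline weeks 1 and 2, 1 and 3, and 2 and 3, against 0.24 to 0.35 within the bleomycin pairs. Camera called 0 of the 36 lists in either, and fry 0 between weeks 3 and 1 and 1 between weeks 2 and 1. The first count was 0 without either 1-week bleomycin pool and 737 without bleomycin pool 2 of week 3. The saline pools correlated across genes at 0.748 for weeks 1 and 2, 0.896 for weeks 1 and 3 and 0.631 for weeks 2 and 3. Differences from saline correlated across genes between weeks at 0.088 for weeks 1 and 2, 0.199 for weeks 1 and 3 and -0.080 for weeks 2 and 3. The expected counts that follow assume independent calls, whereas the weekly comparisons share for each gene the spread from the same bleomycin pairs. The genes called at both 2 and 3 weeks numbered 19 higher, against 1.15 expected, and 1 lower, against 0.261 expected, and 6 were called in opposite directions.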

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

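The comparison of week 2 with the saline pools of weeks 1 and 3, the tests of the array surface and the fits for the 3 pools with many uneven spots are the tests here that were chosen only after the result was seen. Of 50 groups of 4, 6 or 9 values checked for an outlying value 5 had one, where chance gives about 1 in 20 groups. The 35 genes whose bleomycin effect differed between weeks came from the test of that difference itself.

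The saline pool of week 2 had a median correlation of 0.721 with the other pools, and the next lowest was 0.840. The 1893 genes called at 2 weeks kept a median share of 0.0503 of their log2 change (quartiles -0.0988 and 0.253) against the saline pools of weeks 1 and 3, and 791 of 1889 turned round. A candidate explanation is therefore that most of these calls come from the 2-week saline pool and not from bleomycin, though choosing genes by their change against that pool lowers this share by itself. Unevenness over the array surface in 100 blocks is argued against, since with the block means taken off both arrays of that pool the calls kept a median share of 0.993 (quartiles 0.931 and 1.05), and the block means took 0.0204 of the variance on its Cy3 array and 0.0199 on its Cy5 array. A difference in the animals, the tissue taken, the RNA or, apart from the surface, the hybridisation of that pool stays open and was not tested (20.8% of spots were left out on its Cy5 array, and its 2 arrays correlated at 0.769, the lowest of the 9 pools), and Spp1, Tnc, Mmp12 and Retnla were called with both controls.

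The interaction of week and treatment had its smallest adjusted p for Myh11 (0.0127) and Syt7 (0.0165), then Mad1l1, Akt1s1, Klhl1 and Acot1 (0.0241 each) and Lrp5, Smad6, Tpmt and H1f8 (0.0273 each). The saline pool of week 2 lay outside the other saline pools in 35 of the 35 genes called. Bleomycin levels of Myh11 were 0.06, 0.02 and -0.48 at weeks 1, 2 and 3, and saline levels 0.36, -2.43 and 1.09. Since the kept share of 0.0503 was measured on the 2-week calls, which hold all 35 of these genes, the same pool is a candidate explanation here. Over the 35 genes the saline pools had a median range of 2.72 against 0.44 for the bleomycin week means, and no gene was called between bleomycin weeks. The differences thus lay mainly in the saline pools, where 1 pool per week cannot separate a true difference between weeks from a single pool.

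The 76 genes called over all weeks exceeded every other split with 1 control pool drawn per week. Only 1 of the 27 splits, the real one, gave as many, and the highest other gave 0. This is the smallest share that 27 splits can give and lies only just under 0.05, so chance is argued against but not excluded. With no week term, 3 of the 84 splits of the 9 pools gave as many as the real 92, a share under 0.05. Groupings not made by treatment gave more genes than the real one, so this test cannot exclude chance. The highest other called 168 genes, with bleomycin pool 2 of week 2, bleomycin pool 1 of week 3 and the 2-week saline pool drawn as controls, and the next 146, with the 3 pools that had many uneven spots, which points to a structure of the samples. A term for those 3 pools left 3 of the 76 called, and without those pools 2 genes were called, Tnc (2.28 ± 0.17) of the 76 and Vtn (-1.91 ± 0.15) outside them, named after their values were seen, or 16 with no week term as well, 12 of the 76, while 76 of 76 kept their direction in the 3 fits and 76, 76 and 75 an unadjusted p under 0.05. Those 3 pools also had the brightest arrays in each dye orientation, so the 3 fits cannot separate uneven spots from brightness. The 76 were chosen by their p in these same pools. That they kept direction and an unadjusted p under 0.05 was therefore likely beforehand and is no independent support. At 3 weeks both bleomycin pools had many uneven spots. There the calls kept a median share of 0.959 of their log2 change with those spots kept (quartiles 0.840 and 1.01). This argues against the leaving out of spots as the cause of most calls. Genes with no left-out spot keep nearly all of their change in any case, and the share was not split by this. A fault of those slides themselves was not tested and cannot be told apart from bleomycin at that week.

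The share of gene spots left out for uneven pixels was 4.63% on the Cy3 array of bleomycin pool 1 of week 1, and the next highest of the 4 arrays of that group had 1.31%. Arg1 differed from saline by 2.19 on the log2 scale in bleomycin pool 2 of week 2, and by at most 1.12 in the other bleomycin pools. Ager was at 0.77 in bleomycin pool 1 of week 3, and the next highest pool was at -0.14. Top2a was at 0.76 in bleomycin pool 2 of week 2, below the next lowest at 1.04.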

How the results depend on the processing

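Tests with the dye effect taken off each probe, without the 2-week saline pool or its Cy3 array, on genes complete in all pools, against the saline pools of weeks 1 and 3 and for the 3 pools with many uneven spots were chosen only after the results were seen. The settings counted here and elsewhere are not all distinct. Over all weeks, at 3 weeks and for the lists, the fit without the 2-week saline pool is counted 2 times. Aquantile repeats the main values. Over all weeks 2345 of 2903 combinations of named gene and setting kept the direction and the side of the threshold, 463 lost a call, 65 gained one, and in 30 a gene without a call changed sign (Kit -0.19 to 1.31, Sftpc -1.15 to 0.22, Lpin1 -0.54 to 0.03, Zfp36 -0.01 to 0.30, Ccl2 -0.29 to 0.10, Ager -0.70 to 0.33, Pecam1 -0.63 to 0.51 and the saturated Scgb1a1, for which no fold is given), while no called gene did. Tnc passed in 34 of 34 settings, Retnla in 33 of 34 (2.24 to 3.36 on the log2 scale), Spp1 in 30 of 34 (3.11 to 4.95), Col1a2 and Fcer1g in 31 of 34, Ccl9 in 30 of 34, Timp1 in 30 of 33, Mmp12 in 23 of 33, Cd68 in 23 of 34, Top2a in 22 of 34, Igf1 in 21 of 34, Saa3 in 19 of 34, Ctss in 18 of 33, Col5a2 and Msr1 in 17 of 33, Col5a1, Inmt, Ccl12 and Bhlhe40 in 17 of 34, Ccr2 and Cdk1 in 16 of 34, Cst10, Usp48 and Plau in 15 of 34, Acoxl and Gstm1 in 13 of 34, Aspn in 12 of 33, H3c7, Car3 and Clu in 12 of 34, Letm1 in 11 of 34 and Ccn2 in 10 of 34. Changes that moved by over 1.5 times ran on the log2 scale from 1.70 to 4.79 for Mmp12, 1.19 to 2.40 for Ctss, 1.05 to 2.03 for Col5a2, 0.83 to 1.94 for Ccr2, 0.75 to 1.77 for Msr1, 0.70 to 1.38 for Cd68, 0.70 to 1.54 for H3c7, 0.63 to 1.21 for Aspn, 0.55 to 1.30 for Plau, 0.53 to 1.94 for Ccl12, 0.52 to 0.89 for Bhlhe40, 0.49 to 1.66 for Top2a, 0.31 to 1.87 for Cdk1, -2.18 to -0.76 for Letm1, -1.64 to -0.69 for Inmt, -1.36 to -0.52 for Car3, -1.29 to -0.54 for Cst10 and -0.95 to -0.43 for Gstm1. At 3 weeks Tnc passed in 25 of 31, Mmp12 and Crybb3 in 23 of 30, Ctss in 23 of 29, Lox in 22 of 30, Retnla in 21 of 31, Tssk1 in 20 of 29, Gimap6 in 19 of 30, Myh11 in 19 of 31, Serpinc1 in 18 of 30 and Letm1 in 18 of 31. Over 36 settings of the list test the lowest and highest adjusted p were 1.35e-10 and 0.0411 for proteases, 4.61e-18 and 0.0643 for macrophages, 6.12e-08 and 0.0550 for collagens, 5.74e-10 and 0.162 for matrix, 8.17e-05 and 0.135 for basement membrane, 5.36e-07 and 0.288 for TGF-beta, 3.62e-07 and 0.0550 for alternatively activated macrophages, 1.69e-05 and 0.0550 for chemokines, 7.71e-05 and 0.312 for interferon, 0.000148 and 0.738 for complement, 4.50e-06 and 0.0631 for stressed epithelium, 3.29e-14 and 0.297 for club cells, 0.00104 and 0.288 for p53, 6.29e-11 and 0.944 for cell cycle, 0.00237 and 0.414 for antioxidant genes, and 1.30e-07 and 0.214 for cardiac muscle. Of these 16 called lists the cell cycle list alone turned round, with scale normalization (0.944), and lists without a call turned in up to 15 settings (smooth muscle).

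The counts below are numbers of called genes that moved by over 1.5 times, and the cause was not tested unless fewer samples or genes entered. The count over all weeks was 44 with Agilent's processed signals, 29 with no background correction, 33 with median centring, 19 with the Cy3 arrays alone, 242 with all 18 arrays and the pool as a random block, 1750 with array weights (0.15 for the 2-week saline pool and 5.77 for bleomycin pool 1 of week 1), 10 with treat, 283 as the mean of the 3 week-matched contrasts, 20 without the 2-week saline Cy3 array, 25 without that pool, 3 with a term for the 3 pools with many uneven spots and 2 without them. At 1 week it was 1 with scale normalization, 24 with the random block, 1557 with array weights, 1 with the 3 saline pools as 1 control and 392 with the pools of that week alone. At 2 weeks, where 830 of 1893 were higher, it was 1084 with median centring (219 higher), 592 with scale normalization (366 higher), 690 with Cy3 arrays (496 higher), 3073 with Cy5 arrays, 4512 with the random block, 0 with array weights, 290 with treat, 12 with the 3 saline pools as 1 control, 905 with that week's pools alone, 4815 without the 2-week saline Cy3 array and 55 against the saline pools of weeks 1 and 3. Against the latter Nudc (-0.12), Olfr460 (0.35), Syt7 (0.22), Mad1l1 (0.088) and Ift140 (0.0137) turned round.

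At 3 weeks it was 0 with processed signals, 20 with no background correction, 11 with an offset of 16, 13 with scale normalization, 0 with the series table, 6 with Cy3 arrays, 66 with Cy5 arrays, 348 with the random block, 0 with array weights, 15 with treat, 57 with the 3 saline pools as 1 control and 0 with that week's pools alone. Between bleomycin weeks 3 and 1 it was 1 with scale normalization, 1 with Cy3 arrays, 41 with Cy5 arrays, 419 with the random block and 303 with array weights. For the interaction it was 0 with processed signals, 21 with no background correction, 16 with median centring, 4 with scale normalization, 0 with the series table, 69 with uneven spots kept, 0 with Cy3 arrays, 548 with Cy5 arrays, 2325 with the random block, 0 with array weights and 1319 without the 2-week saline Cy3 array. Between saline weeks 3 and 1 it was 13 with the random block and 0 with processed signals, the offset of 16, median centring, the series table, uneven spots kept, either dye alone, array weights, the trended robust prior, treat and the dye effect taken off. Between saline weeks 2 and 1 it was 4 with no background correction, 20 with median centring, 0 with scale normalization, 363 with the series table, 353 with probes above background on all 18 arrays, 418 with uneven spots kept, 138 with Cy3 arrays, 1411 with Cy5 arrays, 2940 with the random block, 0 with array weights, 345 with the trended robust prior, 5 with treat and 3134 without the 2-week saline Cy3 array. The lists called numbered 16 over all weeks, 1 with an estimated correlation and 9 by fry, and 40, 0 and 21 in the same order over the 3 weekly comparisons. The median over the 3 weeks of the correlation of replicate pools, 0.905, was 0.853 with processed signals, 0.892 with an offset of 16, 0.879 with median centring, 0.874 with the series table, 0.882 with Cy3 and 0.870 with Cy5 arrays.

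With 1 pool left out the counts ran from 6 to 102 over all weeks, 0 to 2, 187 to 2830 and 0 to 169 at weeks 1, 2 and 3, 0 to 10 and 0 to 468 between bleomycin weeks 2 and 1 and weeks 3 and 1, 0 to 0 between weeks 3 and 2, 0 to 1 and 0 to 737 between saline weeks 3 and 1 and weeks 2 and 1, and 0 to 151 for the interaction. The lists ran from 13 to 16 and by week from 38 to 46, and the median of the 3 correlations between weeks from -0.00972 to 0.191. With 1 array left out they ran from 20 (2-week saline, Cy3) to 112 (1-week saline, Cy3) over all weeks, 0 to 182 (1-week saline, Cy3) at 1 week, 541 (bleomycin pool 2 of week 1, Cy3) to 4815 at 2 weeks, 2 (bleomycin pool 1 of week 3, Cy5) to 154 (3-week saline, Cy3) at 3 weeks, 0 to 251 (bleomycin pool 2 of week 2, Cy3) between bleomycin weeks 3 and 1, 0 to 6 and 0 to 3134 between saline weeks, and 7 (bleomycin pool 1 of week 1, Cy5) to 1319 for the interaction. The replicate block, fitted to the 6 bleomycin pools, called 0 genes in each comparison of weeks, as did the same pools with no block, and pool numbers did not pair the pools (correlations of 0.141, 0.300 and 0.000744 across 15189 genes). Aquantile left the ratios unchanged, treat gives no interaction value, and a slide block was not run because each slide held 1 array. The lone saline pool of each week limits what every weekly comparison can show, and genes near background or at saturation limit single folds.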

Other observations

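The probe named by its description and 6 of the 36 settings counted here were chosen only after the results were seen. The fibroblast, smooth muscle, endothelial, alveolar and ciliated lists were not called over all weeks. Fibroblast and myofibroblast markers had a median of -0.01 over 14 members (adjusted p = 0.786), with Inmt called lower, 2 higher and 1 lower adjusted over the list alone, and the actin Acta2 of contractile cells at 0.57 ± 0.17 (adjusted p = 0.269), saturated on 5 of the 18 arrays. The list's test pointed up while its median and mean were negative. Smooth muscle markers had a median of -0.06 and a mean of 0.08 (adjusted p = 0.883), with Actg2 at 0.48. Endothelial markers had a median of -0.10 (adjusted p = 0.0936), with Eng at -0.44, Kdr at -0.39 and Pecam1 at 0.02 ± 0.28. The endothelial list was called lower without the 2-week saline pool (-0.31, adjusted p = 5.58e-05) and without bleomycin pool 2 of week 2 (-0.25, adjusted p = 4.01e-05), and turned to 0.16 without the 1-week saline pool (adjusted p = 0.319). It passed in 13 of 36 settings, whose adjusted p ran from 1.01e-08 to 0.790. Alveolar type II markers had a median of -0.05 (adjusted p = 0.244), with Sftpc at -0.62 ± 0.26 on a spot saturated on 9 of 18 arrays, and type I markers a median of 0.23 (adjusted p = 0.394), with Pdpn at 0.76, Igfbp6 at -0.71 and Ager at -0.09 ± 0.21. Without the 2-week saline pool type II markers were called lower (-0.12, adjusted p = 0.0105) and type I markers turned to -0.11 (adjusted p = 0.210). Without the 1-week one type II markers turned to 0.16 (adjusted p = 0.486) and type I markers were called higher (0.60, adjusted p = 0.00610). They passed in 10 and 3 of 36 settings, with adjusted p from 2.51e-06 to 0.936 and from 0.00610 to 0.972. Ciliated cell markers had a median of 0.06 and a mean of -0.09 with the test pointing down (adjusted p = 0.462), and Foxj1 was at -0.45.

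Other immune and stress lists were not called over all weeks either. The median was 0.06 for neutrophils (adjusted p = 0.394), with Ltf at 1.19, and 0.07 for T and NK cells (adjusted p = 0.394), with Gzma at 0.40. It was 0.08 for B and plasma cells (adjusted p = 0.639), with Cd22 at 0.98, and -0.07 for mast cells, eosinophils and basophils (adjusted p = 0.535), with Kit at 0.68. Dendritic cell and MHC class II genes had a median of 0.15 (adjusted p = 0.153), with H2-Ab1 at 0.64 and H2-Oa at -0.81. Without the 2-week saline pool T and NK cell markers were called higher (0.11, adjusted p = 0.0366, in a range over the settings up to 0.972). Without the 1-week one dendritic cell and MHC class II genes were (0.31, adjusted p = 0.0232, in a range from 0.00654 to 0.987). Cytokines had a median of -0.01 and a mean of 0.03 (adjusted p = 0.672), with Il1rn at 0.62. The unfolded protein response had a median of 0.05 (adjusted p = 0.292) with Pdia3 at 0.54, and lipid synthesis -0.03 (adjusted p = 0.786) with Scd1 at 0.48. Immediate early and heat shock genes had a median of 0.00 (adjusted p = 0.867) with Hsph1 at -0.20, and circadian clock genes -0.12 (adjusted p = 0.335), where Bhlhe40 rose (0.77 ± 0.11, adjusted p = 0.0340). Carry-over lists had medians of -0.10 for skeletal muscle (adjusted p = 0.786, Actn3 at 0.43), 0.05 for adipose and mesothelial tissue (adjusted p = 0.672, Lpl at 0.86), -0.09 for thymus and lymphoid tissue (adjusted p = 0.131, Rag2 at -0.29) and -0.03 for erythroid cells (adjusted p = 0.885, Hba-a1 at -0.99 and Bpgm at 0.54). Thymus and lymphoid genes were called lower without bleomycin pool 1 of week 3 (-0.27, adjusted p = 0.0193) and without the 3-week saline pool (-0.25, adjusted p = 0.0272), where 4 of 36 settings passed with 0.0193 as the lowest. A probe described as similar to bleomycin hydrolase, an enzyme that inactivates the drug, was at 0.20 ± 0.14 (adjusted p = 0.713).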
